A study of Homo sapiens with 2 samples.

How the data were processed

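The series holds 1 chromatin immunoprecipitation library and 1 input library from T47D cells, an established oestrogen receptor-positive human breast cancer line. Per the labels' protocols, cells were kept in steroid-depleted medium for 48 h and then given 10 nM 17β-estradiol, the main natural ligand of the receptor, for 45 min. Nuclei were sonicated, and DNA bound by oestrogen receptor α (ERα) was recovered with the H-20 antibody. The input library is sonicated DNA from estradiol-treated cells that went through no antibody step. No untreated library was analysed here, so every value describes occupancy after estradiol and none measures a response to it.

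The deposited file is 1 list of peaks of the ERα library over the input library, and it is the only measurement used. Each row gives a sequence name, a start, an end, a peak name and a score that the authors' peak caller assigned to that peak. The peak names carry the prefix of the MACS caller, per the file, while the submitters' processing notes list CASAVA 1.8, Bowtie 0.12.9, HOMER and the hg19 genome build with no role or order. The caller's version, its threshold, the treatment of duplicate reads and the treatment of reads that map to several places are not given in the sources used here. The scale of the deposited score is not stated either, and it was used only to rank or divide peaks within this list. Per the file, the numbers in the peak names run without a gap from 1 to 12688, as many as there are rows, so no peak was missing from the list as numbered.

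The starts and ends in the deposited file are whole base positions, the starts being counted from 0, and 1 was added to each start for printing. The build was checked against chromosome lengths carried by the R package GenomeInfoDb 1.38.1. The last peak ended past the chromosome end of GRCh38 on 13 chromosomes and past that of hg18 on 18, and past that of hg19 on 0. The read depth of either library is unknown from the file, and no read counts or coverage were used. No level, detection limit or interval that needs a depth is therefore given.

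No hg19 sequence or gene annotation was used here. The gene table at hand follows GRCh38, and coordinates were not carried between builds. For this reason no peak was assigned to a gene. The planned comparisons with promoters, motifs and gene lists were not run, nor was the planned division of motif content by score. The rule for naming items was fixed before the data were examined: without an annotation of the build, the 10 highest-scoring peaks are named. Windows, clusters and other single peaks named in addition were chosen after their values were seen.

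Peaks were counted per chromosome and divided by the hg19 length, with exact Poisson 95% intervals. These intervals cover counting error only and treat peaks as independent, which clustered peaks are not, so each density was also computed after peaks whose edges lay within 10 kb were merged into 1 region. Shares of peaks carry Wilson 95% intervals, which also cover counting error only. Spacing was measured as the share of peaks on chromosomes 1 to 22 and X with another peak centre within 10 kb. It was compared with 1000 random placements of the same number of centres on each chromosome. Further placements kept the number of peaks in every 1 Mb or 100 kb window, or avoided stretches of over 2 Mb without a peak. With 1 library of each kind there is no replicate error, no test between samples was possible, and no p-value is printed. The random placements describe this list only. The spacing measure was tested on simulated data with the 12647 peaks of these chromosomes. Unclustered peaks gave a mean share of 8.71%. Moving 20% of the peaks to 5 kb from another peak gave 44.4%, and 20 of 20 such draws lay above every unclustered draw. Of 50 further unclustered draws, 5 lay above the 95th percentile of the random placements.

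Alternatives were restriction to the 6344 peaks at or above the median score or to the 3172 with the highest scores, merging of peaks, other distances, and restriction to chromosomes 1 to 22 and X. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.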

Results

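ERα binding across the genome was mapped in estradiol-treated T47D cells by sequencing of immunoprecipitated chromatin, with input DNA as the background. The peak list holds 12688 regions, of which 12647 lie on chromosomes 1 to 22 and X, 12 on chromosome Y and 29 on 9 alternative haplotype sequences of the hg19 build. No peak was listed on the mitochondrial genome. The regions were narrow, with a median width of 505 bp (quartiles 412 and 644 bp). On chromosomes 1 to 22 and X they covered 0.238% of the sequence. There was 1 library of each kind, so none of the values below has a replicate error, and the number of reads behind each peak is unknown.

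The peaks differed widely in score. The median score was 128.26 (quartiles 70.54 and 347.16), the lowest was 50 and the highest 3230.05, and 5216 peaks (41.1%) scored under 100. Higher-scoring peaks were wider: the median width was 400.0 bp among the 3172 lowest-scoring peaks and 688 bp among the 3172 highest-scoring ones. Across peaks, which are not independent replicates, the Spearman correlation of width and score was 0.628. The top of the scale was not a smooth ranking. Exactly 235 peaks carried the score 3100, whereas no other score was shared by more than 30 peaks, and 34 peaks scored above it. These 269 peaks with a score of 3100 or more are called strong peaks here.

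The 10 peaks with the highest listed scores lay on 10 different chromosomes. Because so many peaks share the score 3100, they are not shown to be the most enriched of the strong peaks. The first was on chromosome 11 at 45182565 to 45184222 with a score of 3230.05, and the second was on chromosome 10 at 104470098 to 104471021 with a score of 3222.65. The third was on chromosome 14 at 95522619 to 95523580 (score 3219.84), and the fourth on chromosome 12 at 102090905 to 102091821 (score 3214.31). Next came chromosome 20 at 19263899 to 19264762 (score 3213.57) and chromosome 17 at 64948110 to 64949160 (score 3212.27). Peaks on chromosome 4 at 141171105 to 141171820 and on chromosome 8 at 67434165 to 67435291 scored 3210.83 and 3209.00. The last of the 10 were on chromosome 1 at 17846615 to 17847550 (score 3206.41) and on chromosome 2 at 11672240 to 11673178 (score 3203.45). Their widths ran from 716 to 1658 bp. The 235 peaks at exactly 3100 had a median width of 1044 bp, against 941.5 bp for the 34 peaks above that score. The difference of 102.5 bp had a bootstrap 95% interval from -6.0 to 179 bp. The widest peaks at 3100 were on chromosome 16 at 88992466 to 88995847 and on chromosome 8 at 128877852 to 128880986, with widths of 3382 and 3135 bp.

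ERα peaks were unevenly divided among the chromosomes. Chromosome 17 was the densest, with 646 peaks or 7.96 per Mb (exact Poisson 95% interval 7.35 to 8.59), which is 1.91 times the mean of 4.17 per Mb over chromosomes 1 to 22 and X. Chromosomes 19 and 20 followed with 6.66 (6.02 to 7.36) and 6.52 (5.91 to 7.18) per Mb. This order after chromosome 17 depended on the setting. Without peak-free stretches of over 2 Mb, chromosomes 21, 16 and 22 (1.62, 1.505 and 1.41 times the mean) came before 19 and 20 (1.37 and 1.31). After merging within 10 kb, chromosome 20 (1.53) came before 19 (1.47). The sparsest autosomes were chromosome 13 with 2.27 (2.0 to 2.56), chromosome 4 with 2.37 (2.15 to 2.59) and chromosome 18 with 2.42 (2.09 to 2.79) per Mb. Chromosome 1 carried the most peaks, 1169, but its density of 4.69 per Mb (4.43 to 4.97) was 1.13 times the mean.

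In all, 10 of the 23 chromosomes had an interval wholly above the mean density, 7 had one wholly below it, and for 6 the interval included it. These numbers were 8, 9 and 6 when peak-free stretches of over 2 Mb were left out of the lengths: chromosomes 1 and 3 then included the mean, and chromosomes 7 and 12 fell below it. This trimming removes length where peaks are absent, so it is not an independent correction of length. After merging of peaks within 10 kb they were 9, 6 and 8, as chromosomes 5 and 22 then included the mean. The densest and the sparsest autosome differed 3.51-fold. Lengths include unsequenced and repetitive stretches, and no correction for the copy number of chromosomes in T47D cells was made beyond the authors' use of the input. After that merging, the relative density was 1.78 for chromosome 17 and 0.610 for chromosome 13.

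**Figure D1:**
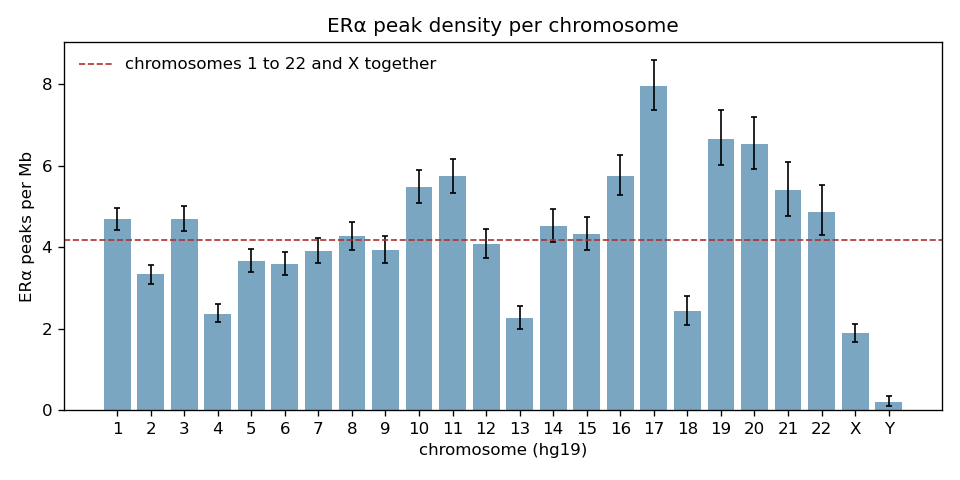
ERα peaks per Mb of hg19 length for each chromosome (bars) with exact Poisson 95% intervals (error bars, counting error only); the dashed line is the 4.17 peaks per Mb of chromosomes 1 to 22 and X together. Chromosome 17 stands highest at 7.96 per Mb, and chromosomes 4, 13, 18, X and Y lie lowest. The bar of chromosome Y counts listed peaks only, and binding there was not tested.

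Chromosome X was sparse in ERα peaks, and a larger share of them scored high than on chromosome 10. It held 292 peaks, or 1.88 per Mb (1.67 to 2.11), which is 0.451 times the mean, or 0.710 times (0.631 to 0.796) with the same trimming of peak-free stretches. Of these, 58.6% (Wilson 95% interval 52.8 to 64.1%) scored at or above the median of the whole list, against 45.7% (42.1 to 49.3%) of the 742 peaks on chromosome 10 (these 2 were picked as the highest and the lowest share of 23 chromosomes). The share on chromosome 18, 57.1% (50.01 to 63.99%), had an interval that overlapped that of X. On chromosome X, 15 of the peaks formed a single cluster, and without it the share on chromosome X was 56.3% (50.4 to 62.0%), below that on chromosome 18. The 12 peaks on chromosome Y, or 0.202 per Mb (0.104 to 0.353), scored at most 143.45 with a median of 62.28. Of the 12, 1 reached the median of the list. The first 2 lay 101429 bp apart, and 1 pair on chromosome X had this spacing within 50 bp. The pair on X began with a centre at 2420948, and the first Y peak ran from 2370786 to 2371199. Of 1000 random spacings of 50 to 150 kb, 22% also had such a pair on X. This check used spacing and not position, so it cannot tell whether the 2 pairs are copies of 1 sequence. Whether the 12 peaks reflect binding on chromosome Y was not tested, and listed positions alone do not show it.

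Within chromosomes, listed peaks were concentrated in some 1 Mb windows. Such counts do not separate many binding sites from wide regions split into several peaks. Copy number was not corrected beyond the authors' use of the input. The window from 85000001 to 86000000 on chromosome 16 held 60 peaks, 4 of them strong, whereas the 1 Mb windows on either side held 21 and 10. On chromosome 10 the window from 79000001 to 80000000 held 42 peaks, and on chromosome 17 the adjoining windows from 38000001 to 39000000 and from 39000001 to 40000000 held 39 and 32. Chromosome 17 had 2 further windows among the 8 densest, from 48000001 with 34 peaks and from 55000001 with 30. Windows from 70000001 on chromosome 15 and from 12000001 on chromosome 6 held 32 and 31 peaks.

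The median 1 Mb window held 2 peaks, and 738 of 3053 windows held 0. At the other end, 60 windows held 20 or more peaks and together 11.6% of all peaks on these chromosomes. The highest count in any window of 1000 random placements was 23.

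**Figure D2:**
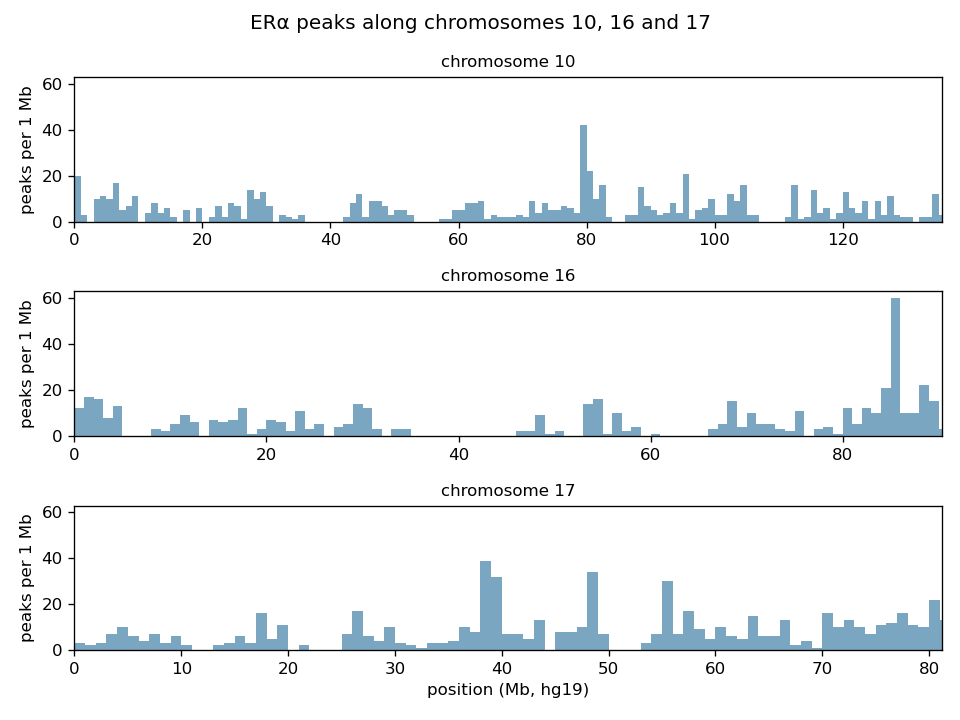
ERα peaks per 1 Mb window (bars) against position in Mb (hg19) along chromosomes 10, 16 and 17, which carry the 3 densest windows. Single windows reach 42, 60 and 39 peaks, while most others hold far fewer.

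The longest stretches between neighbouring peaks were on chromosome 1, from 121421002 to 142539172 (21.1 Mb), and on chromosome 9, from 45463172 to 66485693 (21.0 Mb). Chromosome 16 had 1 of 11.8 Mb, from 34876155 to 46657787. On chromosome X the longest ran from 30166917 to 37764345 and measured 7.60 Mb. In total, 203 peak-free stretches of over 2 Mb took up 760.3 of the 3036.3 Mb of chromosomes 1 to 22 and X. This total includes chromosome ends, which the stretches named above do not. Chromosome lengths include unsequenced and repetitive sequence, which was not marked here, so a stretch without peaks is not shown to lack binding.

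ERα peaks lay close to one another. Of the 12647 peaks, 5234 (41.4%, Wilson 95% interval 40.5 to 42.3%) had another peak centre within 10 kb. Random placements on the same chromosome gave 8.70% ± 0.33 (SD, 1000 placements) and at most 9.69%, so the observed share was 4.75 times the random mean. Placements that kept the number of peaks in every 1 Mb window gave 16.5% ± 0.40 (SD) and at most 17.8%. Keeping the number in every 100 kb window gave 28.3% ± 0.39 (SD) and at most 29.7%.

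**Figure D3:**
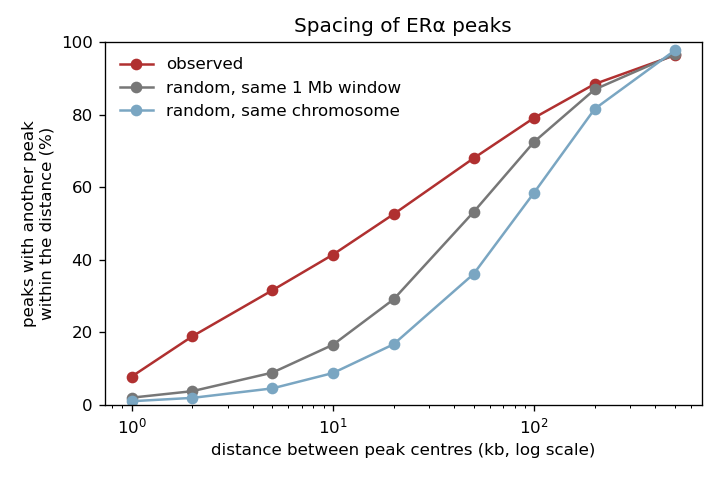
Share of ERα peaks (%) with another peak centre within the distance on the horizontal axis (kb, log scale), for the observed peaks and for means of 100 random placements on the same chromosome or within the same 1 Mb window. At 10 kb the observed share is 41.4%, against 8.70% and 16.5%.

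Merging peaks whose edges lay within 10 kb left 9292 regions on chromosomes 1 to 22 and X. Of these, 7318 held a single peak and 1974 held 2 or more, and 141 held 5 or more with 911 peaks between them. The largest was on chromosome X at 114959568 to 115004411, with 15 peaks in 44.8 kb and a top score of 1058.58. Its peak centres were evenly spaced, 2.69 to 3.88 kb apart. The coefficient of variation of this spacing was 10.7%, against 42.3% or more in the 27 other clusters of 8 or more peaks. A tandem repeat whose units each gave a peak is a candidate explanation. The 15 peaks are therefore not shown to be separate binding sites. A cluster of 14 peaks lay on chromosome 16 at 85309765 to 85356940. There were 3 clusters of 13 peaks, on chromosome 10 at 79614959 to 79667150, on chromosome 15 at 71363268 to 71407517 and on chromosome 17 at 39652955 to 39696998. The cluster on chromosome 2 at 11638468 to 11680372 held 11 peaks, had a median score of 620.94 and included the tenth-ranked peak of the list.

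Peaks with neighbours scored higher than isolated peaks. The 7413 peaks without another peak within 10 kb had a median score of 107.67, and 43.6% of them (Wilson 95% interval 42.5 to 44.8%) scored at or above the median of the list. With 1 neighbour the share was 55.2% (53.4 to 57.0%), with 2 it was 62.4% (59.8 to 65.0%), and with 3 or more it was 65.0% (62.1 to 67.8%). Strong peaks made up 0.80% (0.62 to 1.03%) of the isolated peaks and 6.91% (5.53 to 8.60%) of those with 3 or more neighbours.

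**Figure D4:**
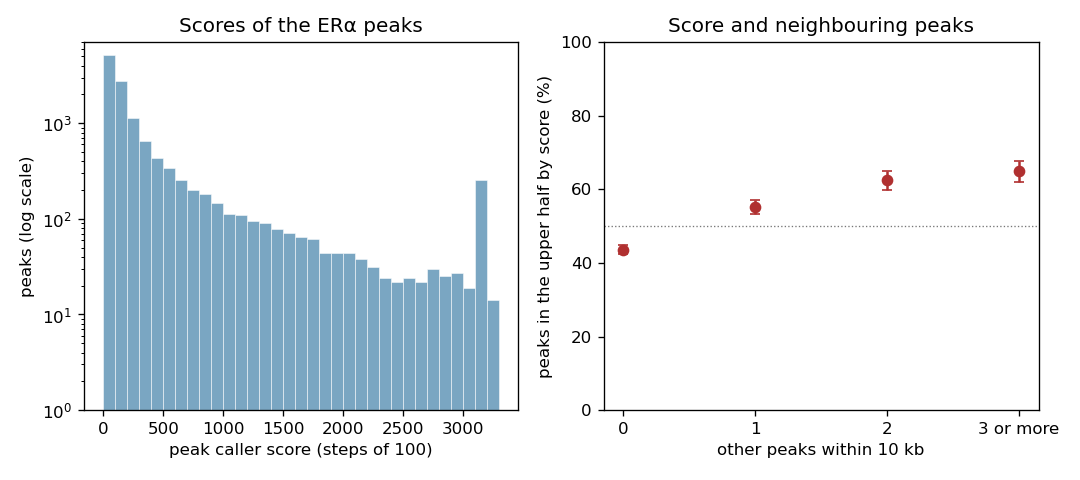
Left, number of ERα peaks (log scale) in steps of 100 of the peak caller score; the step that starts at 3100 stands out with 255 peaks. Right, share of peaks (%) at or above the median score by the number of other peaks within 10 kb, with Wilson 95% intervals (error bars); it goes from 43.6% with 0 neighbours to 65.0% with 3 or more.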

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

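The test in this part was chosen after the result was seen. Besides the primary chromosomes, 29 peaks lay on alternative haplotype sequences, which the comparisons by chromosome leave out: 24 on 7 haplotypes of chromosome 6, 4 on a haplotype of chromosome 17 and 1 on a haplotype of chromosome 4. They drew attention because a similar group of peaks recurred. On 5 of the chromosome 6 haplotypes the highest peak scored between 1974.13 and 2687.48, and the primary chromosome 6 had a peak of 2471.67 at 30719142 to 30719742, followed by peaks 28580 bp and then 10880 bp further on. The haplotype named cox had the same order with distances of 28466 and 10960 bp, and the haplotype named mann with 28587 and 10854 bp. The haplotype named dbb had 28512 and 11273 bp. Those named qbl and ssto had no middle peak, and their next peak lay 39444 and 39441 bp from the first.

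A candidate explanation is that reads from 1 place were shared between near-identical copies of the sequence. Of 17 neighbouring peak pairs on these haplotypes, 11 (64.7%) had a spacing that recurred on another haplotype within 1000 bp. Copies of 1 sequence would show this with shared reads and with separate binding alike, so the share favours neither. The stretch of 4 peaks on the primary chromosome matched 9 of the 17 spacings. The other 12571 stretches of 4 neighbouring peaks matched a median of 0 and at most 8, a narrow margin over the best of them. When the whole peak pattern of a haplotype was slid along the genome, for 5 of 5 haplotypes tried another chromosome matched at least as many peaks (3 or 4) as chromosome 6 did (3). This decides nothing, because a rigid pattern cannot match copies that differ in length. How the authors placed reads that map to several sequences is not given in the sources used here. Which of these haplotypes T47D cells carry is not given either. Shared reads therefore stay a candidate, the recurring peaks are not shown to be separate binding sites, and no biological explanation was tested.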

How the results depend on the processing

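The placements that keep the window counts or avoid peak-free stretches, the shorter chromosome lengths, the band of 2 to 10 kb and the removal of the X cluster were chosen after seeing the data. Of the 12688 peaks, 6344 remained at or above the median score and 3172 among the highest-scoring ones, by construction, while merging within 500 bp left 12006 and chromosomes 1 to 22 and X 12647. The relative density was within its main interval on 21 of 23 chromosomes for the 6344 peaks and on 22 after merging within 10 kb. For the 6344 peaks chromosome X went from 0.451 to 0.529, the interval of chromosome 1 included 1 and that of chromosome 7 lay below it. Leaving out peak-free stretches of over 2 Mb, a choice that depends on the peaks themselves, brought 15 of the 23 outside it: chromosome 17 went to 1.67, chromosome 13 to 0.675 and chromosome X to 0.710, all nearer the mean, while chromosomes 21 and 22 went further from it, to 1.62 and 1.41. Chromosomes 1 and 3 went to 1.02 and 1.01 with intervals that include 1, and chromosomes 7 and 12 to 0.826 and 0.896 with intervals below 1. The spacing share was 31.6% within 5 kb (random mean 4.47%), 68.0% within 50 kb (36.2%), 35.9% for the 6324 of the 6344 peaks on chromosomes 1 to 22 and X (4.44%) and 32.1% for centres 2 to 10 kb apart (7.03%), above all 1000 placements each time. It stood 3.75-fold over placements outside peak-free stretches, 2.51-fold over those within 1 Mb windows and 1.46-fold over those within 100 kb windows. No paired analysis was possible because there is 1 library of each kind. The comparisons with promoters, motifs, gene lists and score against motif, with their alternatives, were not run for want of an hg19 sequence and annotation here. The unknown read depth limits which weak sites could enter the list, and 1 ChIP library gives no error for any peak.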

Other observations

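The tests on the spacing of all peaks and on the shared score were chosen after the peak list had been looked at but before their own results were seen, and the test on the chromosome X cluster after its result. Around the 269 strong ERα peaks, other peaks were far more frequent than in random placements. Within 2 kb there were 130 weaker peaks against a mean of 4.9 in 100 random placements, from 2 to 5 kb there were 147 against 6.8, and from 5 to 10 kb there were 168 against 12. The excess reached further, with 607 against 92.4 from 10 to 50 kb and 805 against 314.2 from 50 to 200 kb. These placements did not keep the number of peaks per window, and the surroundings of weaker peaks were not counted. The excess is therefore not shown to be particular to strong peaks. At the longer distances it may reflect regional density. Across all peaks, 88.5% had another within 200 kb, against 87.0% in placements within 1 Mb windows. The peaks 2 to 5 kb from a strong peak had a median score of 244.80, and 68.0% (Wilson 95% interval 60.1 to 75%) of them scored at or above the median of the list. Within 2 kb the median score was 143.00 and the share 53.1% (44.5 to 61.4%), and beyond 200 kb they were 119.64 and 47.6% (46.6 to 48.5%). Among the 5234 peaks with a neighbour within 10 kb, the score of a peak and that of its nearest neighbour had a Spearman correlation of 0.014 across peaks, within the range from -0.047 to 0.043 of 100 shuffles of the scores within chromosomes.

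The closeness of peaks was weighed against 2 technical explanations. If the caller had only split enriched regions of up to 2 kb, the excess would end at short distances. However, 32.1% of the peaks had another centre 2 to 10 kb away. Random placement gave at most 8.02% in 1000 placements on the same chromosome and at most 14.8% in 1000 within the same 1 Mb window. Splitting of wider regions would also put centres 2 to 10 kb apart, so this band cannot exclude it. If only the density of regions of 1 Mb differed, for example through copy number, placements that keep the number of peaks in each window would reach the observed 41.4%, but the highest of 1000 gave 17.8%. Keeping the number in each 100 kb window gave at most 29.7%. Splitting of regions of up to 2 kb and density at the scale of 1 Mb both fail as the whole cause. Splitting of wider regions stays open, as do differences in copy number, base composition or mappability at scales under 100 kb. No biological explanation was tested, since the design has no second condition.

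The cluster of 15 peaks on chromosome X at 114959568 to 115004411 differed from every other cluster of 8 or more peaks in its even spacing. Its centres lay 3.05 kb apart on average (SD 0.33 kb), a coefficient of variation of 10.7%, whereas the 27 other clusters ran from 42.3 to 133%. All 15 peaks scored between 170.41 and 1058.58. A candidate explanation is a tandem repeat whose units each gave a peak, either through binding in each unit or through reads that fit several units. The sequence was not searched here, so these possibilities stay open, and no biological explanation was tested.

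Of the 15 peaks at least 3 kb wide, 7 scored under 100, against 41.1% of all peaks. Across the list, however, wider peaks scored higher (Spearman correlation 0.628). Upper width quartiles were only 470 bp for scores of 50 to 70.52 and 534 bp for scores of 70.54 to 128.24. The 7 wide peaks with low scores therefore depart from that trend, and the reason was not tested. Chromosome 16 held 5 of the 15, among them neighbours at 85491785 to 85495144 (score 2151.28) and 85495218 to 85500544 (score 2900.82). Whether the wide peaks are broad binding sites was not tested. The widest was on chromosome 8 at 86809525 to 86819075 (9551 bp, score 93.38), with 2 others of 7079 and 6888 bp within the same region. A peak of 7550 bp with a score of 88.66 lay on chromosome 1 at 142535398 to 142542947, the first peak after the 21.1 Mb stretch without any.

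The 235 peaks at a score of exactly 3100 may carry a fill value for p-values too small for the caller to store, in which case they would be wider than the peaks just below and those above that score. Their median width was 1044 bp, against 948 bp for the 19 peaks from 3000 to just under 3100. It was higher by 102.5 bp than that of the peaks above, but the bootstrap 95% interval from -6.0 to 179 bp includes 0, so the test with 34 peaks above the score left this open. If it is so, the peaks with the 10 highest listed scores may not be the strongest.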
